A study of Arabidopsis thaliana with 27 samples.

How the data were processed

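Total RNA from mid-whorl leaves of Arabidopsis thaliana was profiled on 27 Affymetrix ATH1 arrays, a short-oligonucleotide platform on which each probe set reports the abundance of 1 transcript or of several related ones. The plants were Columbia wild type and the double mutant gpa1-4/agb1-2, here called the mutant, which lacks the alpha and beta subunits of the heterotrimeric G protein. Per the labels' protocols, plants 4 to 5 weeks old from a 9 h light and 15 h dark cycle were moved to 4 chambers at 24 degrees C and kept in clean air (5 ppb) or, during 7 h of each day, in ozone at 125 ppb, and leaves were taken after 3 h or after 2 d. The labels do not tie arrays to chambers, so chamber could not be tested as a batch. RNA was extracted with a Qiagen RNeasy kit and biotin-labelled with a MessageAmp II kit, per the labels' protocols. The replicates carry the word biological in the labels, and which plants were pooled for 1 array is not stated there.

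The deposited table holds 1 intensity value per probe set and array, on a linear scale, for 22746 probe sets. Affymetrix Expression Console and RMA are named in the submitters' processing notes, with no versions. The deposited intensity values are not what RMA usually writes, since RMA gives log2 values. Minima lay between 0 and 0.1 and maxima between 22902 and 39907, while the trimmed means of the 27 arrays fell between 495.9 and 496.8 and the medians between 153.5 and 182. Nearly equal trimmed means with unequal medians are the mark of a global scaling to a common mean, but how background, summary and scaling were done is not given in the sources used here. No value was missing, no pair of arrays was identical, and replicate arrays of a group correlated at 0.916 to 0.965 across probe sets.

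The values were taken to log2(intensity + 1) with no further normalization and no filter. Fold changes are therefore on the log2(intensity + 1) scale, which understates the change of dim genes, while scatter between arrays is wide for dim probe sets. One linear model with 8 group means was fitted to all 27 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (19 residual and 2.53 prior degrees of freedom). There were 12 contrasts: ozone against clean air in each genotype at each time, mutant against wild type under each condition, the genotype by ozone interaction at each time, and the ozone by time interaction in each genotype. P-values were 2-sided and adjusted by Benjamini-Hochberg within a contrast, and adjusted p under 0.05 counted as passing. For arrays the number of replicates limits the precision: 3 per group at 3 h and 4 per group at 2 d, except for the mutant in clean air at 2 d with 3. The median standard error of a log2 change was 0.338 for each ozone contrast at 3 h, and at 2 d it was 0.293 in wild type and 0.316 in the mutant.

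Gene names came from the platform annotation, updated through the gene table of assembly TAIR10.1, which was used for names only. Of the probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed there and stay unnamed here. For 77 probe sets with 1 gene the gene number was not in the reference table, and the name of the annotation was kept. Where a gene had several probe sets, the one with the highest mean stood for it in gene lists. Neither GPA1 nor AGB1 was among the named probe sets, so the check of the targeted genes is not analysed here.

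The contrasts, the model, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. By that rule the text takes up to 6 rises and 6 falls per contrast with the largest change among probe sets of 1 gene that passed and whose groups of arrays did not overlap (3 and 3 for the genotype contrasts in ozone and the ozone by time contrasts), and up to 3 members past the threshold per gene list, or 4 where the list as a whole passed. Members of short lists that did not pass are named to describe the list and were chosen after their values were seen. Of the 565 genes on the fixed lists only 77 had a probe set named as 1 gene, and these are called measured. The 14 lists with at least 3 such members were tested. Measured were 4 of 32 WRKY genes, 4 of 18 oxidative stress markers, 8 of 34 glutathione S-transferases and 3 of 31 jasmonate genes. So were 5 of 17 flavonoid, 7 of 34 light harvesting, 6 of 33 antioxidant and 3 of 14 folding genes. A fixed list therefore describes its measured members and not the whole family or pathway. A further 23 lists with 453 members, all tested, were put together from the symbols of the annotation alone after the coverage of the fixed lists was seen and before any test was looked at. Lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated from the arrays. Camera compared a list with the other named genes, with 1 probe set for each of 13355 genes in all. The Benjamini-Hochberg adjustment of camera ran over the fixed lists and over the added lists apart, whereas the plan had 1 adjustment over all lists. The count of members past the threshold is given over all probe sets and, for lists, adjusted over the list alone.

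The model and camera were tested on simulated data for 22746 probe sets, of which 200 were changed by known amounts. Noise was drawn independently for each probe set and array, without correlation between genes or arrays. In the data the estimated correlation was 0.308 for plastid-encoded genes and 0.771 for endoplasmic reticulum folding genes. The simulated recovery and false calls may therefore be more favourable than in the data. For ozone in wild type at 3 h, 26.9%, 70.2% and 95.5% of changes of 1, 2 and 4 on the log2 scale were recovered. For the genotype by ozone interaction the recovery was 8.96%, 47.8% and 77.3% at 3 h, and 13.4%, 52.2% and 78.8% at 2 d. Camera at the preset correlation found 1 list raised by 1 in each of the 12 contrasts, and of the other lists, which were not raised beyond members shared with it and probe sets changed at random, it called 4 for ozone in wild type at 2 d, 2 for ozone in the mutant at 2 d, 1 for the genotype in clean air at 2 d and 1 for the ozone by time interaction in the mutant.

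Alternatives were a second quantile normalization, arrays centred on their median, a filter that left out the third of probe sets with the lowest mean, separate fits per time point, trended and robust moderation, array weights, the replicate number as a block, 1 value per gene, the mean of all probe sets of a gene, an estimated correlation in camera, stricter thresholds and each array left out in turn. A pseudocount of 16 was added after the values were seen to reach 0.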

Results

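Leaf transcripts were measured in wild-type and G-protein null mutant plants in clean air and in ozone, on 27 arrays in 8 groups. At 3 h each of the 4 combinations of genotype and air had 3 arrays. At 2 d wild type had 4 arrays in clean air and 4 in ozone, and the mutant had 3 and 4. The early sampling addressed the first changes on exposure and the late sampling those present after 2 d. Values are log2(intensity + 1), changes carry their standard error (SE) from limma, and group means carry the SD over arrays. Median intensities of 153.5 to 182 mark the middle of the range of each array.

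After 3 h of ozone, most of the probe sets past the threshold in wild-type leaves stood higher. The largest rise was that of AT1G26380, which encodes a berberine-bridge-like FAD oxidase, with 10.02 ± 0.406 in ozone against 4.00 ± 1.25 in clean air (SD, n = 3 each), a change of 6.02 ± 0.955. AT1G19020 rose by 4.76 ± 0.688, from 7.44 ± 0.421 to 12.19 ± 0.766. AT5G12930 rose by 4.69 ± 1.03, the NAC-domain gene AT3G12910 by 4.46 ± 0.806 and AT1G26420, of the same oxidase family as AT1G26380, by 4.37 ± 0.885. The clean-air means of AT3G12910, AT5G12930 and AT1G26380, at 3.24, 3.95 and 4.00, lie near the bottom of the range. Their smallest changes over the runs tried were 3.03, 3.71 and 5.00. The largest falls were smaller, and most of them ended near the bottom of the range. AT4G07660 fell by 2.9 ± 0.583 to a mean of 1.78, AT1G76870 fell by 2.26 ± 0.325 to 3.31 and AT1G04560 fell by 1.99 ± 0.343 to 3.07. With pseudocount 16 these 3 changes were −1.14, −1.32 and −1.06. The adjusted p of limma was 0.004 for AT1G26380, 0.00142 for AT1G19020 and AT1G76870, 0.0152 for AT4G07660 and 0.0061 for AT1G04560.

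Of the 4 WRKY transcription factor genes measured at 3 h in wild type, 2 rose over all probe sets and 3 rose adjusted over the list alone. WRKY6 rose by 4.04 ± 0.686, from 5.13 ± 1.47 to 9.17 ± 0.745, and WRKY53 by 2.71 ± 0.56, from 8.02 ± 0.902 to 10.72 ± 0.942. The changes of WRKY47 and WRKY22, at 1.15 ± 0.397 and 0.26 ± 0.318, did not pass over all probe sets. The list had a median change of 1.93 and passed in camera with adjusted p = 0.000171, and with adjusted p = 0.0393 with an estimated correlation. Among 18 genes of immune receptors and defence signalling, which include these WRKY genes, 3 rose, 15 did not pass and 9 rose adjusted over the list alone. Besides WRKY6 and WRKY53 these were PUB24, a ubiquitin ligase gene, at 1.65 ± 0.35. The median of this list was 1.32 (camera adjusted p = 5.78e-08), and the call was lost at adjusted p = 0.107 with an estimated correlation.

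Other lists moved less firmly in wild type at 3 h. None of the 4 oxidative stress markers passed over all probe sets and 2 rose adjusted over the list alone. STZ, a zinc-finger gene, stood 2.71 ± 0.693 higher and the glucosyltransferase gene UGT73B5 2.29 ± 0.583 higher in ozone. The median was 2.06 with camera adjusted p = 0.0451, lost at adjusted p = 0.287 with an estimated correlation. This call was also lost without clean-air replicates 2 and 3 (camera adjusted p = 0.103 and 0.1) and without ozone replicates 1, 2 and 3 (0.0544, 0.115 and 0.071). All 5 measured flavonoid and anthocyanin genes, DFR and UGT78D2 among them, stood lower, with a median of −1.32, but 0 passed in limma over all probe sets or adjusted over the list alone. Their camera adjusted p of 0.0451 became an adjusted p = 0.734 with an estimated correlation, and without clean-air replicate 2 or ozone replicates 1, 2 and 3 it was 0.47, 0.0544, 0.0677 and 0.217. The co-chaperones of HSP70 and HSP90 had a median of 0.56 over 11 genes with 0 past the threshold and 1 higher adjusted over the list alone, and camera adjusted p = 0.027 was lost at adjusted p = 0.251 with an estimated correlation. This call also failed without clean-air replicate 2 and without ozone replicates 1 and 2. UGT71B6 and UGT71C1 rose by 4.03 ± 0.756 and 3.12 ± 0.754, alone among 47 glycosyltransferase genes, whose list did not pass (camera adjusted p = 0.11); their clean-air means of 2.31 and 3.35 lie near the bottom of the range, and with pseudocount 16 the changes were 2.33 and 2.14. CYP71B23 rose by 2.03 ± 0.482, the autophagy gene ATG8H by 1.32 ± 0.31 and the calmodulin-like gene CML42 by 1.36 ± 0.224, while the carboxypeptidase-like gene SCPL49 fell by 0.80 ± 0.172.

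In total 342 probe sets passed in limma for ozone in wild type at 3 h, 274 higher and 68 lower, of which 180 had 1 named gene. Of these 342, 339 had no overlap between the 3 ozone and 3 clean-air arrays, where chance gives 10% of unselected probe sets. Probe sets chosen for a small p-value mostly separate by that choice, so here and below this adds no support. The share of higher calls was 80.1%, against 54.3% with array weights and 60.6% without ozone replicate 3. With separate fits per time point the calls of AT3G12910, AT1G26420, AT4G07660, AT1G04560, WRKY53, PUB24, UGT71C1, CYP71B23 and SCPL49 were lost. So were those of AT3G52170, AT3G50420 and AT1G49000, which rose by 4.2 ± 1.07. The count depended on single arrays. It was 145, 138 and 80 without clean-air replicates 1, 2 and 3, and 59, 73 and 1230 without ozone replicates 1, 2 and 3. Of the 21 named genes of this comparison 6 passed whichever array was left out, namely AT1G26380, AT1G19020, WRKY6, AT1G76870, AT1G04560 and CML42.

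The mutant showed rises in many of the same genes at 3 h. AT5G12930 rose by 4.79 ± 1.03, AT1G26380 by 4.74 ± 0.955, from 4.83 ± 1.97 to 9.57 ± 0.901 (SD, n = 3 each), AT1G26420 by 4.72 ± 0.885 and AT1G19020 by 4.35 ± 0.688. The receptor kinase gene AT1G51850 rose by 3.84 ± 0.787 from a clean-air mean of 1.90 (1.91 with pseudocount 16) and AT3G02840 by 4.00 ± 0.69. AT5G12930 and AT1G26420 started from low clean-air means of 3.66 and 3.81. Their smallest changes over the runs tried were 3.72 and 3.64. Falls were few: ATMND1 fell by 2.67 ± 0.453 to a mean of 2.32 (−1.20 with pseudocount 16) and LCR69, a defensin-like gene, fell by 1.65 ± 0.364. Adjusted p in limma was 0.00825 for AT1G19020, 0.0237 for AT1G26380 and 0.0106 for ATMND1.

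Of the WRKY genes in the mutant at 3 h, 2 rose over all probe sets and 2 rose adjusted over the list alone: WRKY6 by 3.17 ± 0.686 and WRKY53 by 2.48 ± 0.56. The list had a median of 1.64 and camera adjusted p = 0.000423, or adjusted p = 0.0469 with an estimated correlation. Of the 4 oxidative stress markers 1 rose, UGT73B5 by 3.35 ± 0.583, and 2 rose adjusted over the list alone. Their median of 2.50 had camera adjusted p = 0.00147 and adjusted p = 0.0469 with an estimated correlation. Among immune receptors and defence signalling 3 of 18 rose, 9 rose adjusted over the list alone and the median was 1.24 (camera adjusted p = 1.3e-10, and adjusted p = 0.0347 with an estimated correlation), with PUB24 rising by 1.75 ± 0.35. The flavonoid and anthocyanin genes had a median of −1.94 with 0 of 5 past the threshold in limma, also adjusted over the list alone, and their camera adjusted p of 0.00147 was lost at adjusted p = 0.247 with an estimated correlation and without clean-air or ozone replicate 2 (0.0536 and 0.0739). Of 11 co-chaperones Hsp70-2 rose by 3.11 ± 0.696 and Fes1A by 2.9 ± 0.666, while the list did not pass (camera adjusted p = 0.0629). UGT71B6 rose by 3.36 ± 0.756 from a mean of 2.88 and CYP71B23 rose by 2.34 ± 0.482. With pseudocount 16 the change of UGT71B6 was 2.01 and its call was lost.

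For ozone in the mutant at 3 h, 148 probe sets passed in limma, 140 higher and 8 lower, and 79 had 1 named gene. Of the 148, 147 had no overlap between the 3 and 3 arrays, where chance gives 10% of unselected probe sets. The count was 13, 296 and 3 without clean-air replicates 1, 2 and 3, and 92 and 4 without ozone replicates 1 and 2, while none of the 16 named genes passed under every array left out. With arrays centred on their median it was 91, and the calls of UGT71B6, Fes1A, Hsp70-2 and WRKY53 were lost, those of UGT71B6 and Fes1A also with a second quantile normalization. With separate fits per time point it was 52, and of the 16 named genes AT5G12930, AT1G19020, AT1G51850 and AT3G02840 kept their call.

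After 2 d of ozone another set of genes stood out in wild type. AT2G44240 rose by 5.45 ± 1.25, from 3.96 ± 0.926 to 9.41 ± 2.14, and AT3G28510 by 5.25 ± 1.33 (SD, n = 4 each). CHI (AT2G43570), a putative chitinase gene, rose by 4.73 ± 0.915, from 8.46 ± 0.869 to 13.19 ± 0.142. AMY1, an alpha-amylase gene, rose by 3.99 ± 0.567, from 7.03 ± 0.74 to 11.02 ± 0.603, LUP5, of the lupeol synthase family, by 3.99 ± 0.976 and the aspartyl protease gene AT1G44130 by 3.74 ± 0.759. AT1G23050 fell by 3.05 ± 0.593, AT1G12010, an ACC oxidase-like gene, by 3.00 ± 0.687, AT5G13140 by 2.91 ± 0.616 and AT1G78450 by 2.78 ± 0.505. AT2G10940 fell by 2.77 ± 0.672 from a high level of 13.37 ± 0.271. The ozone means of AT1G23050 and AT1G12010, 2.81 and 2.76, lie near the bottom of the range, and with pseudocount 16 their changes were −1.78 and −1.66. The clean-air means of AT3G28510 and AT2G44240, 3.43 and 3.96, are low as well. Their smallest changes over the runs tried were 3.96 and 4.48. Adjusted p in limma was 0.00447 for AMY1, 0.0141 for CHI and AT1G23050, and 0.0241 for AT2G44240.

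Plastid-encoded transcripts were lower in wild type at 2 d. Of 69 measured genes 20 fell and 0 rose in limma, 54 fell adjusted over the list alone, and 68 of 69 changes were below 0. psbD, which encodes the D2 protein of photosystem II, fell by 1.59 ± 0.372, ycf3 by 1.52 ± 0.298, and rpoC1 and rpoC2, subunits of the plastid RNA polymerase, by 1.46 ± 0.386 and 1.32 ± 0.315. The median of the list was −0.80 (camera adjusted p = 1.06e-23), and the call was lost at adjusted p = 0.198 with an estimated correlation. Taken as 1 value per array, the median of these genes was 11.16 ± 0.37 in ozone and 11.82 ± 0.0929 in clean air (SD, n = 4 each), without overlap. A 2-sided exact permutation test gave p = 0.0286, the smallest p that 4 against 4 arrays can give. This p was not adjusted for the number of lists or contrasts. It comes from the same arrays as the camera call, so it adds no independent support.

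**Figure D1:**
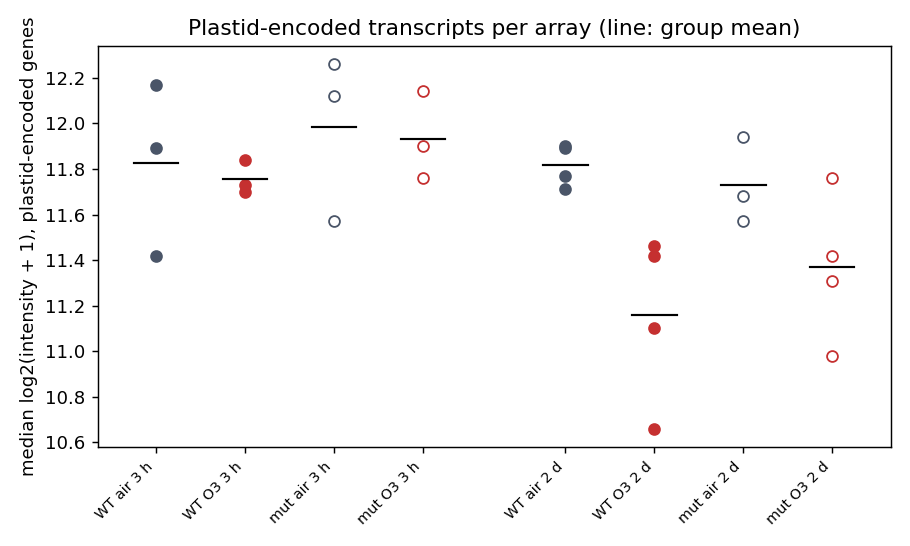
Median log2(intensity + 1) of the 69 plastid-encoded genes on each of the 27 arrays (vertical axis) by group (horizontal axis; WT, wild type; mut, mutant; air, 5 ppb; O3, 125 ppb ozone), with 1 point per array and a line at the group mean. The 4 wild-type ozone arrays at 2 d, at 10.66 to 11.46, lay below the 4 clean-air arrays, at 11.71 to 11.9.

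Nuclear genes of photosynthesis stood lower as well in wild type at 2 d, but fewer passed. Of 7 light harvesting and photosystem genes 0 passed in limma over all probe sets, 4 fell adjusted over the list alone and all were below 0, with PSAN at −0.77 ± 0.259 and LHCB4.1 at −0.29 ± 0.178. Their median was −0.64, with camera adjusted p = 0.0052 lost at adjusted p = 0.522 with an estimated correlation and at 0.0505 without clean-air replicate 3. All 12 genes of tetrapyrrole and chlorophyll synthesis were below 0 (median −0.68), 0 passed over all and 7 fell adjusted over the list alone, with camera adjusted p = 0.000707 and adjusted p = 0.26 with an estimated correlation. The 3 Calvin cycle genes had a median of −0.37, with 0 past the threshold, 1 lower adjusted over the list alone and camera adjusted p = 0.154. Of 7 tubulin genes TUB1 and TUB7 fell by 1.49 ± 0.373 and 1.48 ± 0.318, 5 fell adjusted over the list alone, and the median was −0.85 (camera adjusted p = 0.0015, and adjusted p = 0.198 with an estimated correlation). TBL45 and TBL38, of a family that O-acetylates cell wall polysaccharides, fell by 1.92 ± 0.427 and 1.05 ± 0.271 among 37 genes of that list, which did not pass (camera adjusted p = 0.0891).

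Single genes of protein folding and redox metabolism passed in wild type at 2 d. Of 3 endoplasmic reticulum folding genes CRT1b, a calreticulin gene, rose by 1.68 ± 0.407 from 10.82 ± 0.0668, and ATERDJ3B, a J-domain co-chaperone gene, by 1.42 ± 0.394. All 3 rose adjusted over the list alone, the median was 1.42 and camera adjusted p = 0.00232 was lost at adjusted p = 0.386 with an estimated correlation. Among 6 antioxidant genes TAPX, the thylakoid ascorbate peroxidase, fell by 1.51 ± 0.267, from 11.38 ± 0.188 to 9.87 ± 0.402, and GR1, a glutathione reductase, rose by 1.07 ± 0.211, so that 1 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.608). None of the 8 glutathione S-transferases measured, of 34 listed, passed, over all or adjusted over the list alone. Their median was −0.17 (camera adjusted p = 0.608), with GSTU20 at −0.06 ± 0.293, which leaves the unmeasured members open. Immune receptors and defence signalling had a median of 0.82 with ATLP-1, a thaumatin-like gene, the 1 of 18 past the threshold, falling by 1.57 ± 0.351. Adjusted over the list alone 6 rose and 1 fell, and camera adjusted p = 0.000707 was lost at adjusted p = 0.26 with an estimated correlation. Of 10 autophagy genes ATG8B rose by 1.19 ± 0.214, also adjusted over the list alone, and the median of 0.27 had camera adjusted p = 0.00854, lost at adjusted p = 0.262 with an estimated correlation. The co-chaperones had a median of 0.26 with 0 of 11 past the threshold and 2 higher adjusted over the list alone, and camera adjusted p = 0.0401 was lost at adjusted p = 0.26 with an estimated correlation, with a second quantile normalization and without clean-air replicates 3 and 4 or ozone replicates 1 and 4. CML42 fell by 0.93 ± 0.194, and ACLA-2 and ACLA-1, subunits of ATP-citrate lyase, fell by 1.13 ± 0.262 and 0.62 ± 0.158.

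For ozone in wild type at 2 d, 784 probe sets passed in limma, 370 higher and 414 lower, and 430 had 1 named gene. Of the 784, 726 had no overlap between the 4 and 4 arrays, where chance gives 2.86% of unselected probe sets. The count was 221, 96, 402 and 457 without clean-air replicates 1, 2, 3 and 4, and 64 and 184 without ozone replicates 2 and 3. Of the 37 named genes 5 passed whichever array was left out: AMY1, AT1G23050, AT1G78450, TAPX and ATG8B. With a second quantile normalization the calls of TUB1, TBL38 and ATERDJ3B were lost, and with separate fits per time point those of TBL38 and rpoC1.

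In the mutant at 2 d, AMY1 rose by 4.11 ± 0.613, from 7.34 ± 1.07 (SD, n = 3) to 11.45 ± 0.4 (SD, n = 4), and AT1G26420 by 4.08 ± 0.828. SAL2, an inositol phosphatase gene, rose by 3.44 ± 0.693, AT3G46770 by 2.98 ± 0.559, AT5G52740 by 2.9 ± 0.581 and AT5G05840 by 2.81 ± 0.454. TBL41 and TBL38 fell by 2.33 ± 0.455 and 1.5 ± 0.293, the only 2 past the threshold among the 37 genes of that list, over all and adjusted over the list alone. AT1G19530 fell by 2.32 ± 0.43 to a mean of 0.98, at the bottom of the range, and its change was −0.60 with pseudocount 16, where the call was lost. With pseudocount 16 the changes of AT1G26420, AT5G05840 and TBL41 were 2.51, 1.58 and −1.5. A second quantile normalization ended the calls of AT1G26420, SAL2, AT3G46770, AT5G52740, TBL41, TBL38 and AT1G19530, and centred arrays ended the first 4 of these. Adjusted p in limma was 0.0133 for AMY1, 0.0219 for AT5G05840 and 0.0403 for TBL41.

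Several lists passed in camera in the mutant at 2 d with few or no single genes past the threshold. The plastid-encoded genes had a median of −0.37, with 63 of 69 below 0, 0 passing in limma over all and 1 falling adjusted over the list alone. Their camera adjusted p of 2.68e-12 was lost at adjusted p = 0.246 with an estimated correlation, and their medians per array, 11.37 ± 0.322 (SD, n = 4) in ozone and 11.73 ± 0.19 (SD, n = 3) in clean air, overlapped, with p = 0.143 in a 2-sided exact permutation test. The TBL list had a median of −0.34 (camera adjusted p = 0.00678, and adjusted p = 0.246 with an estimated correlation). Tubulins had a median of −0.52, with 0 of 7 past the threshold and 2 lower adjusted over the list alone (camera adjusted p = 0.00026, and adjusted p = 0.159 with an estimated correlation). Light harvesting genes had a median of −0.39 with 0 of 7 past the threshold, also adjusted over the list alone, and camera adjusted p = 0.00398 was lost at adjusted p = 0.294 with an estimated correlation and with a second quantile normalization. The 3 endoplasmic reticulum folding genes had a median of 1.12, with 0 past the threshold and 2 higher adjusted over the list alone, and camera adjusted p = 0.028 was lost at adjusted p = 0.294 with an estimated correlation and without clean-air replicate 1 (0.0814) or ozone replicate 3 (0.0895).

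Jasmonate genes and others were of the same kind in the mutant at 2 d. The 3 fixed jasmonate genes, PDF1.2 (−1.66 ± 0.771), JMT (−1.34 ± 0.452) and THI2.1 (−0.59 ± 0.507), had 0 past the threshold and 1 lower adjusted over the list alone. Their camera adjusted p of 0.0289 was lost at adjusted p = 0.294 with an estimated correlation and without clean-air replicate 3 or ozone replicates 1 and 3. The wider list of 11 jasmonate genes had a median of −0.50 (camera adjusted p = 0.0369, and adjusted p = 0.246 with an estimated correlation), also lost with arrays centred and without clean-air replicate 3 or ozone replicates 1 and 2. The 3 aliphatic glucosinolate genes, with UGT74B1 at 0.53 ± 0.17, had a median of 0.53, 0 past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.294 with an estimated correlation), and kept the call only without clean-air replicate 2 or ozone replicate 4 among the arrays left out. The tetrapyrrole genes had a median of −0.36 and 0 of 12 past the threshold, and camera adjusted p = 0.0251 was lost at adjusted p = 0.53 with an estimated correlation, with a second quantile normalization and without clean-air replicates 1 and 2 or ozone replicates 1 and 2. Co-chaperones had a median of 0.41, with 0 of 11 past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.00678, and adjusted p = 0.246 with an estimated correlation).

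For ozone in the mutant at 2 d, 43 probe sets passed in limma, 35 higher and 8 lower, 28 with 1 named gene. Of these, 43 had no overlap between the 4 and 3 arrays, where chance gives 5.71% of unselected probe sets. The count was 0, 2 and 18 without clean-air replicates 1, 2 and 3, and 0, 0, 176 and 4 without ozone replicates 1, 2, 3 and 4; at unadjusted p under 0.05 limma called 2801 with all arrays. With arrays centred on their median it was 18, of which 10 were higher and 8 lower, a share of 55.6% higher against 81.4%, and with a second quantile normalization it was 15.

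**Figure D2:**
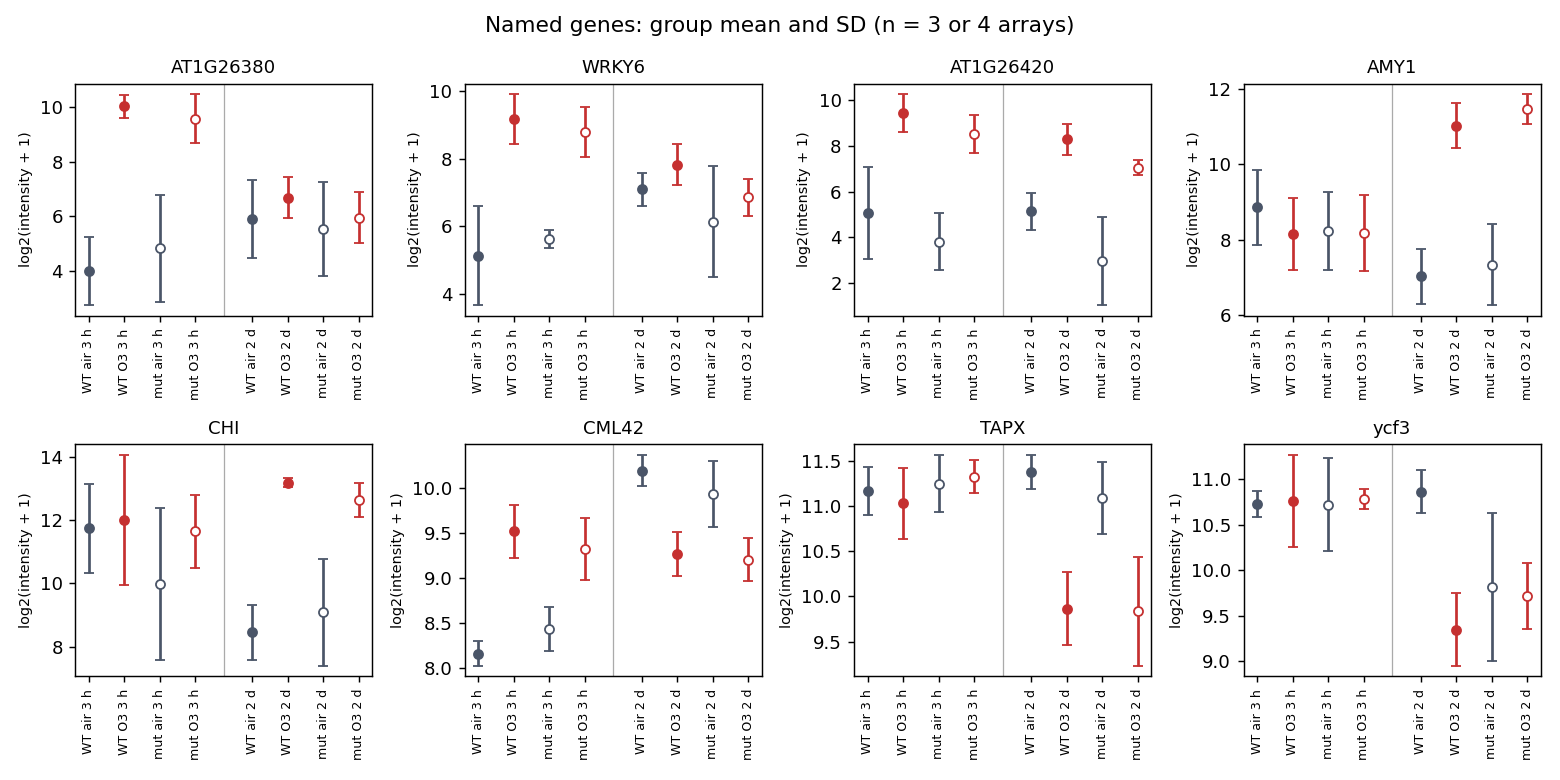
Mean log2(intensity + 1) (vertical axis) with SD bars for 8 named genes in the 8 groups (horizontal axis; filled, wild type; open, mutant; grey, 5 ppb; red, 125 ppb ozone; n = 3 or 4 arrays), with the 3 h groups to the left of the line and the 2 d groups to the right. AT1G26380 reached 10.02 in wild type and 9.57 in the mutant after 3 h of ozone, and AMY1 reached 11.02 and 11.45 after 2 d.

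The responses of both genotypes were set side by side to ask whether the loss of the G protein alters the response to ozone. No gene differed in its response at the threshold. In the genotype by ozone interaction limma called 0 probe sets at 3 h (627 at unadjusted p under 0.05, smallest adjusted p = 0.436) and 0 at 2 d (646 at unadjusted p under 0.05, smallest adjusted p = 1). AT4G07660, the gene that fell by 2.9 in wild type at 3 h, stood 1.60 ± 0.583 higher in ozone in the mutant (adjusted p = 0.276), and the difference of 4.50 ± 0.825 had that smallest adjusted p of 0.436. Its mean was 4.68 in wild-type clean air at 3 h and 1.23 to 2.83 in all other groups, near the bottom of the range. Its fall in wild type, its genotype difference in clean air at 3 h and this difference all share that 1 group. The interaction at 3 h gave 1 call without wild-type clean-air replicate 2 or mutant ozone replicate 1. Among lists, only the plastid-encoded genes passed in camera, at 2 d with a median difference of 0.36 (adjusted p = 4.63e-05), lost at adjusted p = 0.52 with an estimated correlation and without mutant ozone replicate 3.

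Many calls were shared between the genotypes. At 3 h 96 probe sets were called higher in both, where lists drawn independently would share 1.69, and 2 were called lower in both against 0.0239. At 2 d 25 were called higher in both against 0.569 and 4 lower in both against 0.146. Of the wild-type calls, 268 of 274 higher and 63 of 68 lower at 3 h, and 366 of 370 higher and 399 of 414 lower at 2 d, had the same sign in the mutant, and 0 were called in opposite directions in limma. Across all probe sets the log2 changes of mutant and wild type correlated with r = 0.532 at 3 h (jackknife SE 0.15) and r = 0.538 at 2 d (jackknife SE 0.153), a description across genes, which are not independent replicates. Among the genes called in both at 3 h were AT1G26380, AT1G26420, AT1G19020, WRKY6 and WRKY53, of which AT1G19020 kept both calls with separate fits per time point. At 2 d AMY1, AT1G26420 and TBL38 were called in both, but with a second quantile normalization AT1G26420 lost its call in the mutant and TBL38 in both genotypes. TAPX, called in wild type at 2 d, had a change of −1.26 ± 0.288 in the mutant (adjusted p = 0.0697) and CHI one of 3.56 ± 0.988 (adjusted p = 0.126).

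**Figure D3:**
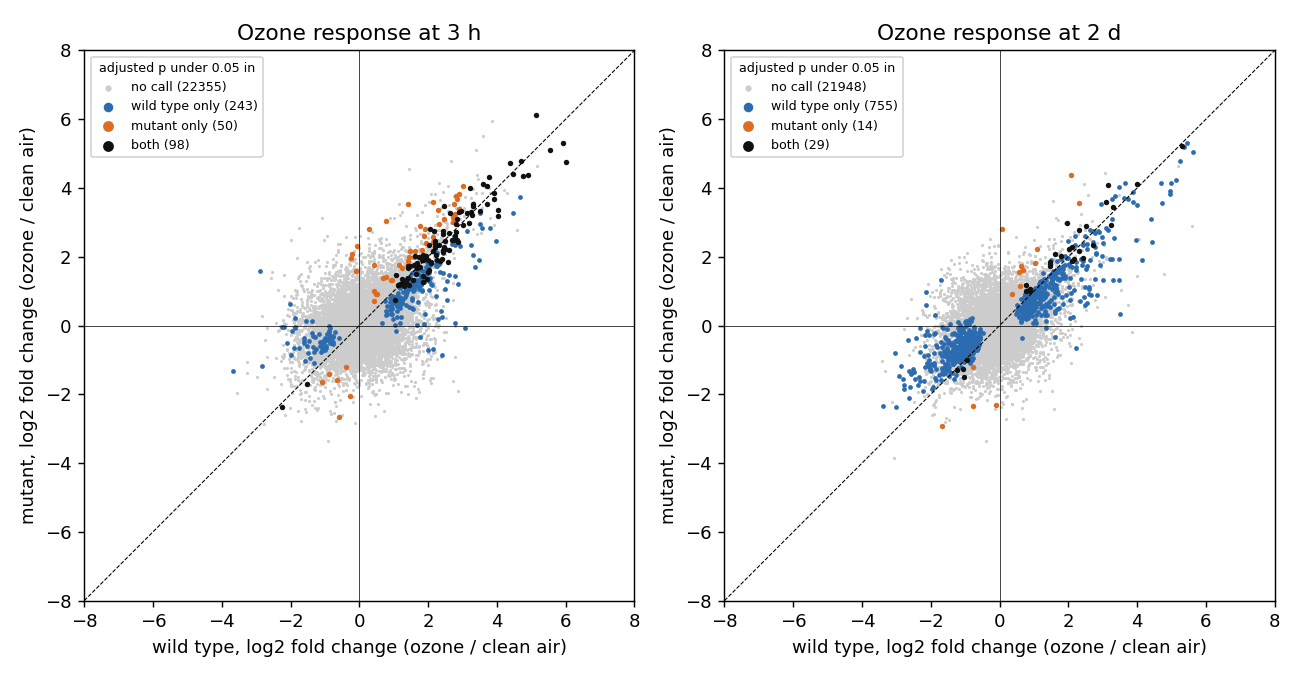
Log2 fold change of ozone against clean air in wild type (horizontal axis) and in the mutant (vertical axis) for 22746 probe sets at 3 h (left) and 2 d (right), coloured by adjusted p under 0.05 in either or both genotypes, with a dashed line of equal response. The probe sets called in both genotypes, 96 higher and 2 lower at 3 h and 25 higher and 4 lower at 2 d, lie in the upper right and lower left of each panel.

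Few transcripts passed between mutant and wild-type leaves under any one condition with all arrays weighted equally, while array weights gave 1085 in ozone at 3 h (491 higher and 594 lower). In that run wild-type ozone replicates 1, 2 and 3 had weights of 3.6, 0.538 and 0.358. The wild-type side of the 1085 therefore rests mostly on 1 array. The probe sets 267375_at and 253204_at, which have no gene in the annotation used here, were lower in the mutant under all 4 conditions. For 267375_at the difference was −5.82 ± 0.649 in clean air at 3 h, −6.55 ± 0.607 in clean air at 2 d, −7.18 ± 0.649 in ozone at 3 h and −6.44 ± 0.562 in ozone at 2 d, and the level was 8.16 to 9.67 on the 14 wild-type arrays against 1.26 to 4.90 on the 13 mutant arrays. For 253204_at it was −2.16 ± 0.278, −2.05 ± 0.26, −3.11 ± 0.278 and −2.50 ± 0.241 in the same order, with levels of 9.92 to 11.36 on wild-type arrays and 7.69 to 8.83 on mutant arrays. Adjusted p in limma for 267375_at was 0.000231 in clean air at 3 h and 2.84e-06 in ozone at 2 d. Its mutant means, 1.895 to 2.8, lie near the bottom of the range, so the sizes of its differences are not exact. These probe sets were singled out after their values were seen.

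The named genes past the threshold between the genotypes were called under 1 condition each, and no change of these differences between conditions passed where it was tested, in the genotype by ozone interaction. AT4G07660 was lower in the mutant in clean air at 3 h, with a difference of −3.45 ± 0.583 (1.23 ± 0.539 against 4.68 ± 0.168, SD, n = 3 each), with an adjusted p just under 0.05 in limma. AT4G11400 was higher in the mutant in clean air at 2 d by 2.08 ± 0.335 (adjusted p = 0.0248), and stood 1.34 ± 0.31 higher in ozone at 2 d (adjusted p = 0.563). At 3 h it stood 0.62 ± 0.358 higher in clean air but 0.91 ± 0.358 lower in ozone, neither past the threshold. AT5G47790 and AT1G76870 were higher in the mutant in ozone at 3 h by 2.23 ± 0.377 and 1.90 ± 0.325 (adjusted p = 0.0447 each). Their means in wild-type ozone at 3 h, 4.56 and 3.31, lay below those of all other groups, at 6.51 to 7.50 and 5.21 to 5.65. The differences of both genes and their falls in wild-type ozone at 3 h share that 1 group. None of these calls between the genotypes held under each array left out. That of AT4G07660 was lost without each of the 6 arrays and with a second quantile normalization, separate fits or trended and robust moderation, and its change was −1.22 with pseudocount 16. That of AT4G11400 was lost without wild-type replicates 2 and 4 or mutant replicates 2 and 3 and with separate fits or trended and robust moderation, and its change was 1.29 with pseudocount 16. In ozone at 3 h the call of AT1G76870 was lost without wild-type replicates 2 and 3 or mutant replicates 1 and 2 and with separate fits, trended and robust moderation or pseudocount 16 (1.06), and that of AT5G47790 without any array but mutant replicate 3 and with separate fits or pseudocount 16 (1.71). In total limma called 3 probe sets in clean air at 3 h, 3 in clean air at 2 d, 4 in ozone at 3 h and 2 in ozone at 2 d. All were without overlap, which the choice by p-value largely brings about. For unselected probe sets chance gives 10% with 3 against 3 arrays, 5.71% with 3 against 4 and 2.86% with 4 against 4. Without wild-type clean-air replicate 1 the count in clean air at 3 h was 5. In ozone at 3 h the count was 8 without wild-type ozone replicate 2, 2 without mutant ozone replicate 1 or 2 and 13 without mutant ozone replicate 3, and a second quantile normalization gave 66.7% higher calls (4 higher and 2 lower) in place of 50% (2 and 2).

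Gene lists differed little between the genotypes, and every list call was lost with an estimated correlation. In clean air at 3 h the autophagy genes had a median of 0.11 (adjusted p = 0.498 with an estimated correlation), plastid-encoded genes of 0.07 (0.616), tetrapyrrole genes of 0.21 (0.498), branched-chain amino acid breakdown of 0.20 (0.325) and cold and dehydration genes of 0.26 (0.325), with camera adjusted p from 0.0249 to 0.0263 at the preset correlation. All 5 were lost with a second quantile normalization and without wild-type clean-air replicate 1, the plastid median was −0.0964 without wild-type replicate 3 and −0.0558 without mutant replicate 1, and the autophagy median was −0.056 without mutant replicate 2. In clean air at 2 d the plastid-encoded genes had a median of −0.18 (adjusted p = 0.935 with an estimated correlation). In ozone at 3 h their median was 0.15 (0.875) and in ozone at 2 d it was 0.17 (0.716). In ozone at 2 d the 3 early auxin genes had a median of −0.55 with 0 past the threshold in limma (adjusted p = 0.147 with an estimated correlation), immune receptors and defence signalling of −0.30 (0.293), autophagy genes of −0.30 (0.293) and glycosyltransferases of −0.06 (0.293). The median of the glycosyltransferases changed sign, to 0.0167, without the third of probe sets with the lowest mean.

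The early and late responses to ozone differed in wild type. AMY1 stood 4.69 ± 0.867 higher in its 2 d response than in its 3 h response (adjusted p = 0.0202 in limma), AT1G32740 4.31 ± 1.01 and AT1G51380 3.68 ± 0.833 higher. The difference was −5.24 ± 1.26 for AT1G26380 (adjusted p = 0.0448), −5.81 ± 1.43 for AT4G17240 and −5.13 ± 1.19 for AT3G23550. With 1 of 14 arrays left out the call was kept 12 times for AMY1 (lost without clean-air replicate 1 at 3 h and ozone replicate 2 at 2 d), 4 times for AT1G32740, 5 times for AT1G51380 and 2 times each for AT1G26380, AT4G17240 and AT3G23550. AT4G17240 also lost its call with a second quantile normalization. With pseudocount 16 the differences of AT4G17240 and AT1G32740 were −3.35 and 2.34. For the plastid-encoded genes the median difference was −0.70 (camera adjusted p = 7.43e-12), lost at adjusted p = 0.664 with an estimated correlation. The median over all probe sets was −0.115. Limma called 283 probe sets, 153 higher and 130 lower. The count was 23, 161 and 110 without clean-air replicates 1, 2 and 3 at 3 h, 98 and 117 without ozone replicates 1 and 3 at 3 h, 111, 131, 116 and 145 without clean-air replicates 1, 2, 3 and 4 at 2 d, and 97, 25, 135 and 692 without ozone replicates 1, 2, 3 and 4 at 2 d.

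In the mutant fewer probe sets differed between the early and the late response. AT5G05840 stood 3.99 ± 0.665 higher and AT1G60770 1.68 ± 0.281 higher in the 2 d response (adjusted p = 0.0221 each in limma), and AT3G46110 differed by −2.71 ± 0.489 (adjusted p = 0.0446). With 1 of 13 arrays left out these calls were kept 7, 7 and 3 times, and that of AT3G46110 was lost with a second quantile normalization and with arrays centred. With pseudocount 16 the difference of AT5G05840 was 2.53. The oxidative stress markers had a median difference of −2.37 (camera adjusted p = 0.0306, and adjusted p = 0.253 with an estimated correlation), immune receptors and defence signalling of −0.92 (0.00111, and adjusted p = 0.515 with an estimated correlation) and plastid-encoded genes of −0.39 (1.23e-07, and adjusted p = 0.703 with an estimated correlation). The call of the oxidative stress markers failed without ozone replicate 3 at 3 h (0.092), clean-air replicate 3 at 2 d (0.137) or ozone replicates 1 and 2 at 2 d (0.0525 and 0.0902). Limma called 8 probe sets, 2 higher and 6 lower. The count was 3, 20 and 0 without clean-air replicates 1, 2 and 3 at 3 h, 5 without ozone replicate 3 at 3 h, 4 without clean-air replicate 2 at 2 d, and 4, 3 and 49 without ozone replicates 1, 2 and 3 at 2 d. At unadjusted p under 0.05 limma called 2656 with all arrays. The difference between the genotypes in this contrast was not tested.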

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

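Of the tests below, the one on nuclear photosynthesis genes and the one on the third wild-type ozone array at 3 h were chosen after the result was seen.

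Plastid-encoded transcripts stood lower after 2 d of ozone in wild type, with a median of −0.80 over 69 genes, and the difference to the 3 h response was −0.70 in wild type and −0.39 in the mutant. A brightness-dependent bias of the arrays was argued against, since nuclear genes matched on brightness had a median of −0.0277. Of 10000 matched random lists 0 came as low, the lowest at −0.357. These lists were matched on brightness alone, while the plastid-encoded genes had an estimated correlation of 0.308. The 0 of 10000 therefore does not measure how often a correlated list falls as far. The scaling was argued against as the whole source, since the median was −0.763 with each array centred on its median. A fall of photosynthesis transcripts of both genomes may be part of the pattern: the higher of the medians of light harvesting and tetrapyrrole genes was −0.635, but neither list kept its call with an estimated correlation, so this stays open. Whether the labelling takes up plastid transcripts evenly was not tested.

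Fewer probe sets were called for ozone at 2 d in the mutant (43) than in wild type (784). A single unusual mutant clean-air array cannot be told apart from the rest: without any one of them the mutant had at most 18, but wild type too had at most 457 without 1 clean-air array. With 3 clean-air and 4 ozone arrays, the numbers of the mutant, wild type had 96 to 457 calls, each time above 43. By the rule fixed before, these counts go against fewer mutant clean-air arrays as the explanation. It is still left open here, on a ground added afterwards, since the counts swung widely with single arrays. The 96, and the 64 of wild type without ozone replicate 2, lie inside the range of 0 to 176 of the mutant with 1 array left out. An unusual mutant ozone array stays open too, since 176 came without replicate 3. A smaller ozone response in the mutant is a candidate explanation: of the 500 probe sets with the largest summed response 67.8% responded less in the mutant, and 51.4% to 76.6% with 1 array left out, the lowest without mutant clean-air replicate 3. No probe set passed in the interaction, so the size of the difference is not settled for any gene, and the median difference of the plastid-encoded genes was 0.36.

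The third wild-type ozone array at 3 h lay nearest the clean-air arrays, and leaving it out took the count in wild type at 3 h from 342 to 1230. Its score, the mean over the 148 probe sets called in the mutant with the 8 called lower entered as negative, was 8.05, against 8.93 and 9.01 on the other ozone arrays and 6.33 to 6.72 on the clean-air arrays. A clean-air array with an ozone label was argued against, since it lay 1.33 above the highest clean-air array. In array weights it had 0.358, the lowest of the 27, while replicates 1 and 2 had 3.6 and 0.538. With array weights the values of this group therefore rest mostly on replicate 1. A weaker exposure or a chamber effect was not tested, because the labels do not tie arrays to chambers.

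The early and the late response of single genes differed by a test of the difference itself. In wild type the differences were 4.69 for AMY1, 4.31 for AT1G32740, 3.68 for AT1G51380, −5.81 for AT4G17240, −5.24 for AT1G26380 and −5.13 for AT3G23550. In the mutant they were 3.99 for AT5G05840, 1.68 for AT1G60770 and −2.71 for AT3G46110. Lists that differed between the times in the mutant were the oxidative stress markers (median −2.37) and immune receptors and defence signalling (median −0.92), which lost their calls with an estimated correlation.

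Single arrays stood apart from the other 3 of their group in 8 of 132 groups of 4 that were tested, where chance gives about 1 in 20. AT2G10940 was 12.81 on wild-type ozone replicate 1 at 2 d (others 9.69 to 9.99) and 12.96 on wild-type clean-air replicate 4 (13.44 to 13.53). TUB1 was 4.21 on wild-type ozone replicate 3 at 2 d (5.31 to 5.45), and AT3G48490 was 6.29 on mutant ozone replicate 1 (7.35 to 7.52). The light harvesting median was 13.4 on wild-type ozone replicate 3 (12.98 to 13.01) and 13.97 on wild-type clean-air replicate 3 (13.53 to 13.6). The tetrapyrrole median was 11.38 on mutant ozone replicate 3 (10.92 to 10.93), and the co-chaperone median was 8.96 on mutant ozone replicate 1 (8.57 to 8.61).

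Other splits of the same arrays were tried for each count. For ozone in wild type at 2 d chance can be excluded, with 784 calls against at most 9 in the others of 35 splits. The ozone by time interaction in the mutant had 8 calls against at most 5 in the others of 100 splits. In wild type 2 of 100 splits, the real one included, gave at least its 283 calls, and the other had 711. Any regrouping for these contrasts mixes arrays of different air or times, so it also breaks up the ozone or time effects. These splits therefore cannot exclude chance for the ozone by time interactions. For the counts of ozone in the mutant at 2 d (43 against 61) and of the genotype at 2 d in clean air (3 against 218, reached in 4 of 35 splits) and in ozone (2 against 4) chance cannot be excluded, although the 2 unnamed probe sets among the genotype calls were lower on each of the 13 mutant arrays than on any of the 14 wild-type arrays. Nor can the splits test the genotype by ozone interactions, since with 0 calls in limma (627 and 646 at unadjusted p under 0.05) all 100 splits are as large by construction. The highest other had 1331 at 3 h and 19 at 2 d. At 3 h the 10 splits of 3 against 3 arrays are too few for a share under 0.05, with 342 against 14 for ozone in wild type, 148 against 1 in the mutant, 3 against 1 for the genotype in clean air and 4 against 400 in ozone. Splits that called 218 and 400 probe sets point to a structure among the arrays other than the groups compared. Deviations shared in part by replicate number, described below, are a candidate. Whether they gave these splits was not tested. The 711 and 1331 came from interactions, where a regrouping can put the ozone response itself into the contrast. They therefore need no such structure.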

How the results depend on the processing

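The pseudocount of 16 and the added gene lists were chosen after seeing the data, the other alternatives before. Per array 12.21% to 17.15% of probe sets lay below an intensity of 16, where signal stands little over background. For each change below the cause was not tested, except that 1 value per gene and the brightness filter test fewer features, and stricter thresholds call fewer by construction. Counts are given for ozone in wild type at 3 h, the mutant at 3 h, wild type at 2 d and the mutant at 2 d, in this order, then for the ozone by time interaction in wild type and mutant. Without the third of probe sets with the lowest mean they were 542, 234, 1319, 117, 515 and 52, with array weights 3329, 844, 2191, 424, 2067 and 306, with 1 value per gene 149, 73, 372, 27, 86 and 2, and at adjusted p under 0.01 in limma 54, 8, 12, 0, 5 and 0. The 3329 and 2067 with array weights lean on wild-type ozone replicate 1 at 3 h, which had a weight of 3.6. Separate fits per time point gave 145 and 52 at 3 h and 117 in the mutant at 2 d. A second quantile normalization gave 15 and centred arrays 18 in the mutant at 2 d, and centred arrays 91 in the mutant at 3 h. In the mutant at 2 d trended and robust moderation gave 101 and pseudocount 16 gave 76, and in its ozone by time interaction 21 and 24. A log2 change of at least 1 left 483 in wild type at 2 d.

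The genotype counts in clean air at 3 h and 2 d and in ozone at 3 h and 2 d were 1, 1, 2 and 1 with the brightness filter and 0, 1, 0 and 0 with 1 value per gene. Array weights gave 14 and 7 in clean air and 1085 in ozone at 3 h, separate fits 2 and 4 in ozone, and adjusted p under 0.01 gave 2 in ozone at 3 h. The 1085 lean on the same wild-type ozone replicate 1. Both genotype by ozone interactions stayed at 0 in limma under every alternative except arrays left out (627 and 646 at unadjusted p under 0.05). The correlation of responses was 0.798 with the brightness filter and 0.693 with pseudocount 16 at 3 h, and 0.766 with the filter at 2 d. Of the 12 calls of fixed lists for ozone, 7 passed with the filter and 3 with an estimated correlation.

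With 1 array left out the counts ran from 59 to 1230 (wild type at 3 h), 3 to 296 (mutant at 3 h), 64 to 971 (wild type at 2 d), 0 to 176 (mutant at 2 d), 2 to 5 and 2 to 4 (genotype in clean air), 2 to 13 and 2 to 3 (genotype in ozone), 0 to 1 and 0 to 0 (interactions), and 23 to 692 and 0 to 49 (ozone by time). The correlations ran from 0.418 to 0.565 and from 0.382 to 0.578, lowest at 2 d without mutant clean-air replicate 1, and the list calls from 9 to 12. The 99 calls of named genes, some of them called in several comparisons, kept direction in all runs and were kept in 676 of 755 runs under other settings and 319 of 750 with an array left out. The 44 list calls were kept in 350 of 435 and 261 of 339, and the median or direction of 3 lists reversed, none of which had a call there. For the genotype in clean air at 3 h the plastid median was −0.0964 without wild-type clean-air replicate 3 and −0.0558 without mutant replicate 1 (up to 0.226 without other arrays), and the autophagy median was −0.056 without mutant replicate 2 (up to 0.259). For the genotype in ozone at 2 d the glycosyltransferase median was 0.0167 with the brightness filter.

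Replicate numbers did not pair the arrays throughout: 7 of 18 same-number pairs at 3 h and 9 of 21 at 2 d had correlated deviations over 0.1 (lowest −0.0606 and −0.0866), and 7 of 12 and 6 of 15 arrays correlated best with their own number. As a hint from the data, the median correlation was 0.0323 for the same number against −0.0364 for other numbers at 3 h, and 0.0693 against −0.0435 at 2 d. Mutant clean-air replicates 2 and 3 at 2 d correlated at 0.139 to 0.25 with the next higher number and at −0.0866 to 0.00487 with their own. Replicate 1 of that group correlated at 0.147 to 0.184 with number 2 and at −0.0469 to 0.214 with its own. At 3 h wild-type clean-air replicate 1 correlated at 0.0699 to 0.203 with number 2 and at −0.059 to 0.0295 with its own. The block follows the labels' numbers, so its counts, those of the interactions included, leave another pairing untested. With the number as a replicate block the counts were 890, 407, 1299, 150, 564 and 212 in the order above, 2, 2, 3 and 2 for the genotype, and 0 for both interactions. Of the named genes, AT4G07660, AT4G11400 and AT1G76870 (genotype) and AT1G26420 (mutant at 2 d) lost their call with the block.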

Other observations

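The added gene lists were put together after the data were seen, before any test was looked at, and CML37 and the lists that did not pass were picked for this part after their values were seen. Some genes called in wild-type leaves after 2 d of ozone were not described above, and CML42 was described without its levels. CML42, the calmodulin-like gene that rose by 1.36 ± 0.224 at 3 h, fell by 0.93 ± 0.194 at 2 d, with levels of 8.16 ± 0.136 and 9.52 ± 0.294 in clean air and ozone at 3 h (SD, n = 3 each) and of 10.20 ± 0.174 and 9.27 ± 0.241 at 2 d (SD, n = 4 each). The P450 genes CYP71B26 and CYP71B23 rose by 2.35 ± 0.524 and 1.72 ± 0.418, 2 of 19 in their list (3 rose and 2 fell adjusted over the list alone), which did not pass (camera adjusted p = 0.254). Among 29 carboxypeptidase-like genes scpl25 fell by 1.3 ± 0.269 and scpl46 rose by 0.99 ± 0.24. SWEET6, a sugar transporter gene, fell by 0.99 ± 0.267 as 1 of 14, and AGL87, a MADS-box gene, fell by 1.51 ± 0.38 as 1 of 40. DI21, of the dehydration list, rose by 1.57 ± 0.435, and WES1, an auxin-conjugating enzyme gene of the early auxin list, rose by 0.94 ± 0.244, also adjusted over the list alone. The arrays of SWEET6, DI21 and WES1 overlapped between ozone and clean air. SWEET6 lost its call with a second quantile normalization, centred arrays and separate fits, and CYP71B26, DI21 and WES1 with separate fits. Each of these calls at 2 d, that of CML42 included, was lost without wild-type ozone replicate 2 and without clean-air replicate 2, and most were lost without further arrays.

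Calcium-related and cell wall genes gave values without calls. CML37 stood 3.34 ± 0.919 higher in wild type and 3.59 ± 0.919 higher in the mutant after 3 h of ozone, one of 2 measured genes of MAP kinase and calcium signalling, of which 0 passed in limma over all probe sets while 1 in wild type and 2 in the mutant rose adjusted over the list alone. All 8 fixed expansin and xyloglucan genes lay below 0 in wild type at 2 d, with a median of −0.51 and 0 past the threshold in limma, over all or adjusted over the list alone (camera adjusted p = 0.268). The 20 beta-glucosidase genes had a median of 0.24 at that time, with 0 past the threshold in limma and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.178).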
